A study of Mus musculus with 20 samples.

How the data were processed

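The 20 libraries were RNA-seq of PDGFRb+ cells of inguinal white adipose tissue of male C57BL/6 mice, isolated by flow cytometry and sorted by DPP4, 5 libraries each for DPP4+ and DPP4- cells from mice at 22 °C or at 6 °C for 24 h. Per the labels, RNA was prepared with an RNAqueous micro kit and libraries with a NEBNext Ultra II kit. Per the submitters' processing notes the tools were Trim Galore 0.4.1, HISAT2 2.0.1, featureCounts 1.4.6 and DESeq2 1.6.3, with the builds GRCm38 and mm10 named and with no role or order given. The annotation and the strand of the libraries are not stated, so overlapping and antisense genes cannot be told apart. The deposited signal is a table of normalized counts per gene and library, made by the authors by dividing the gene counts of each library by 1 factor. It was checked that 100% of the values are whole multiples of a single step per library (tolerance 0.1 read, largest distance 0.00054), which gave back the whole reads.

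The table held 27179 genes, with 958 lacking a symbol, which took 0.0610 to 0.0824% of the reads of a library. Symbols that a spreadsheet had turned into dates (26 of them) were restored from a RefSeq table by gene ID, in which 25275 IDs were found. Coordinates are those of the same RefSeq table on GRCm38. GC content and transcript length were taken from the GENCODE vM21 annotation. Reads per library ranged from 8.49 to 18.8 M (1 M is 1e+06 reads), with means of 16.5 ± 0.783 M in DPP4+ cells at 22 °C, 14.2 ± 2.47 M in DPP4+ cells at 6 °C, 12.3 ± 1.10 M in DPP4- cells at 22 °C and 12.5 ± 3.78 M in DPP4- cells at 6 °C (SD, n = 5). The biological coefficient of variation (edgeR) was 0.0746 to 0.124 per group.

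Genes with a mean of at least 10 normalized reads over all libraries, 13057, were tested on log2(value + 1) with limma 3.58.1 (linear model of 4 group means, 16 residual degrees of freedom, moderated variances with a trend on mean level and robust estimation) in R 4.3.3. The contrasts were cold against 22 °C in each population, the difference of these effects, and DPP4+ against DPP4- cells at each temperature, 5 in all. P-values were two-sided and adjusted by Benjamini-Hochberg within each contrast, with a threshold of 0.05. Folds given as ratios are ratios of group means, and log2 differences are fitted values on the log2(value + 1) scale. Where all libraries of a group were at 0 the ratio was computed against 3 reads over the group and is a lower bound, and where a group held 1 to 3 reads a 95% interval is given; floors and intervals cover counting error only. The gene lists, 44 in number, were tested with limma camera, with a preset correlation between genes of 0.01 and again with an estimated correlation, adjusted over the 40 lists with at least 3 tested members. Mitochondrially encoded genes (0 of 13 tested), mesothelial markers (2 of 12), erythroid markers (0 of 8) and epithelial markers (1 of 12) were too few to test. Counts of list members adjusted over the list alone apply Benjamini-Hochberg to the members.

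Genes named in the text followed a rule. For each contrast it took the 12 largest rises and the 12 largest falls among genes past the threshold whose groups of 5 did not overlap and whose higher group had a mean of at least 50 normalized reads. For the difference of the cold effects the groups were not required to be apart. Predicted genes without an established symbol were passed over. Up to 4 members of each list with the smallest p-values were added, and Dpp4, Pdgfrb, Pdgfra, Ucp1, Il33, Ccl2, Adrb1 and Adrb3 were always included. Some genes that the rule names are not reported here. The groups, contrasts, lists, naming rule and alternatives to each choice were set before the data were examined. The groups of 5 were apart for 5008 genes (38.4%) in DPP4+ cells, 636 (4.87%) in DPP4- cells, 8461 (64.8%) between the populations at 22 °C and 7461 (57.1%) in the cold, where chance gives 0.794%.

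The procedure was tested on simulated data, in which 67, 67 and 66 of 13057 genes changed 1.5-fold, 2-fold and 4-fold. At 1.5-fold limma recovered 65.7% in the comparison in DPP4+ cells, 68.7% in DPP4- cells, 52.2% for the difference, 71.6% between the populations at 22 °C and 76.1% in the cold. At 2-fold it recovered 86.6%, 94.0%, 83.6%, 88.1% and 85.1%, and at 4-fold 97.0%, 98.5%, 93.9%, 98.5% and 100%, in the same order. False calls numbered 4 of 170 calls, 18 of 192, 6 of 159, 18 of 190 and 9 of 183. The changed list was called in each while 0 of 39 unchanged lists were. The simulated genes were independent, far fewer changed than were called in the data, and the populations did not differ otherwise. Scaling and correlation between list members were therefore not tested by it. Counts of called genes were repeated on the whole reads with the edgeR 4.0.16 quasi-likelihood test and DESeq2 1.42.0. In the order above edgeR called 3344 genes higher and 3215 lower, 243 and 371, 2160 and 2190, 5028 and 4802, and 4964 and 4771. DESeq2 called 3328 and 3272, 322 and 586, 2282 and 2235, 4915 and 4891, and 4837 and 4817.

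The alternatives were other pseudocounts, filters, scalings, sample weights, tools and model scopes, a block for the replicate number, and each library left out in turn. Totals set equal between libraries, a correction for GC content and transcript length, thinning of reads and the removal of 2 libraries were added after the data were seen. The labels do not say whether libraries come from separate animals beyond being separate samples, so the p-values measure the spread between these samples. Label parsing and figures used Python 3.11.15 and matplotlib 3.10.9.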

Results

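Gene expression was measured by RNA-seq in adipocyte progenitor cells (APCs) of inguinal white adipose tissue, the subcutaneous fat depot of the mouse groin. PDGFRb+ cells of male C57BL/6 mice had been sorted by flow cytometry and divided by DPP4, a cell surface peptidase, into DPP4+ and DPP4- cells. The mice had been housed at 22 °C or at 6 °C for 24 h, which gave 4 groups of 5 libraries and 20 libraries in all. Reads assigned to genes ranged from 8.49 to 18.8 M per library (1 M is 1e+06 reads). The range was 15.8 to 17.6 M in DPP4+ cells at 22 °C and 11.8 to 17.5 M in DPP4+ cells at 6 °C. In DPP4- cells it was 11.0 to 13.4 M at 22 °C and 8.49 to 18.8 M at 6 °C. Of 27179 genes, 13057 had a mean of at least 10 normalized reads and were tested with limma on the log2(value + 1) scale. The first principal component, with 76.2% of the variance, separated DPP4+ from DPP4- libraries, and the second, with 10.5%, separated DPP4+ libraries at 6 °C from those at 22 °C.

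**Figure D1:**
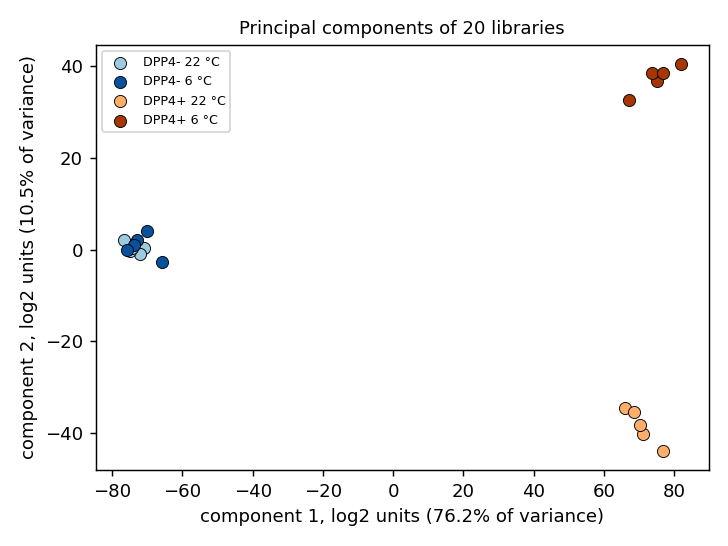
Principal components of the 20 libraries on log2(value + 1) of all tested genes, component 1 on the x axis and component 2 on the y axis, both in log2 units; each point is 1 library, coloured by group. Component 1 (76.2% of the variance) parts DPP4+ from DPP4- libraries, and component 2 (10.5%) parts the temperatures in DPP4+ cells. On both, the DPP4- libraries of the 2 temperatures lie together. They are apart on component 4 (1.82% of the variance), which is not drawn.

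Which genes mark the sorted populations was addressed first in mice kept at 22 °C. Dpp4 itself (Entrez gene 13482, GRCm38 chromosome 2, 62330073 to 62412315), the sort marker, stood at 8546 ± 1158 normalized reads (SD, n = 5) in DPP4+ cells and at 67.9 ± 21.6 (n = 5) in DPP4- cells, a 126-fold difference (adjusted p = 1.6e-13, limma). Pi16, a peptidase inhibitor known from interstitial fibroblasts, was 107-fold higher at 30115 ± 5621, and Bmp7, a bone morphogenetic protein, was 278-fold higher at 478 ± 77.0. Cemip, which degrades hyaluronan, reached 12532 ± 1286 against 8.54 ± 7.04, and the ligand Wnt16 reached 437 ± 51.3 against 1.94 ± 0.791. In the other direction, the matrix protein Sparcl1 stood at 26775 ± 2770 in DPP4- cells and at 369 ± 79.6 in DPP4+ cells, and Lamc3, a laminin chain of basement membranes, was 441-fold higher in DPP4- cells. Cox8b, a cytochrome oxidase subunit of heart, muscle and brown fat, had 106 ± 16.4 normalized reads in DPP4- cells and none in the 5 DPP4+ libraries, at least 263-fold lower against a floor of 3 reads over the group.

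All 18 DPP4+ interstitial progenitor markers, Dpp4 among them, were higher in DPP4+ cells (18 adjusted over the list alone; median log2 difference 3.72), with Sema3c, a secreted semaphorin, at 6642 ± 684 against 1140 ± 89.5. The DPP4+ marker list had adjusted p = 3.11e-08 (limma camera), and adjusted p = 0.336 with an estimated correlation. Of 17 committed preadipocyte markers, 14 were lower in DPP4+ cells and 2 higher (14 and 2 adjusted over the list alone; median -2.02), among them the basement membrane collagens Col4a1 (11009 ± 523 against 172400 ± 18898) and Col15a1 (2136 ± 189 against 45254 ± 2044). This list passed with both corrections (adjusted p = 1.82e-06, limma camera; adjusted p = 0.0428 with an estimated correlation). Of 12 CD142+ progenitor markers, 10 were lower and none higher (10 lower and 1 higher adjusted over the list alone), including the growth factors Gdf10 (1576 ± 243 against 12833 ± 616) and Clec11a (142 ± 17.7 against 1799 ± 150). The CD142+ list had adjusted p = 0.000389 (limma camera), and adjusted p = 0.477 with an estimated correlation. Wnt ligands, inhibitors and target genes were higher in 21 of 28 cases and lower in 4 (21 and 4 adjusted over the list alone), with the Wnt inhibitors Apcdd1 at 899 ± 43.1 against 172 ± 15.8 and Sfrp1 at 13903 ± 1289 against 1680 ± 145. The Wnt list also passed with both corrections (adjusted p = 9.94e-05, limma camera; adjusted p = 0.0428 with an estimated correlation).

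Cell cycle genes were higher in DPP4+ cells in 32 of 33 cases, with 1 lower (32 and 1 adjusted over the list alone; median 4.28). Prc1, a protein of the mitotic spindle, had 782 ± 89.9 normalized reads against 22.9 ± 8.57, the mitotic kinase Aurka 178 ± 18.2 against 7.25 ± 1.97, and the replication helicase subunit Mcm5 280 ± 44.3 against 23.5 ± 1.07. The cell cycle list had adjusted p = 6.88e-12 (limma camera), and adjusted p = 0.196 with an estimated correlation. Immediate early and tissue dissociation genes, which are switched on when tissue is taken apart, were lower in 25 of 27 cases and higher in 1 (25 and 1 adjusted over the list alone; median -1.85). They included the transcription factor Egr1 (5993 ± 656 against 36792 ± 2902), the cytokine feedback inhibitor Socs3 (4080 ± 803 against 22058 ± 2893) and the chaperone Dnajb1 (967 ± 59.8 against 5538 ± 528). The immediate early list had adjusted p = 1.56e-09 (limma camera), and adjusted p = 0.35 with an estimated correlation. Interferon-stimulated genes were lower in 24 of 27 cases and higher in none (24 and none adjusted over the list alone; median -2.11), with the antiviral GTPase Mx2 at 58.8 ± 7.65 against 446 ± 67.5 and the signal transducer Stat2 at 1107 ± 52.1 against 3262 ± 198. The interferon list had adjusted p = 1.56e-09 (limma camera), and adjusted p = 0.484 with an estimated correlation. Ribosome biogenesis genes were lower in 24 of 28 cases and higher in 1, the same counts as adjusted over the list alone, among them the transcription factor Myc (3125 ± 510 against 10746 ± 1025). The ribosome biogenesis list had adjusted p = 2.5e-06 (limma camera), and adjusted p = 0.538 with an estimated correlation. Markers of pericytes and smooth muscle moved apart beside these groups: 7 of 15 were higher in DPP4+ cells, among them the contractile genes Acta2 (6046 ± 641 against 45.6 ± 21.7), Tagln (3700 ± 423 against 74.9 ± 33.9) and Cnn1 (211 ± 17.1 against 2.25 ± 0.885). Another 6 were lower, with the pericyte markers Ndufa4l2 at 2.37 ± 1.45 against 178 ± 28.4 and Abcc9 at 222 ± 60.9 against 2558 ± 392. As a whole this list did not pass (adjusted p = 0.583, limma camera). Some markers of other cell types were also lower in DPP4+ cells. Lymphocyte markers summed to 61.4 ± 14.7 against 258 ± 69.5 and granulocyte and mast cell markers to 17.7 ± 1.79 against 135 ± 157. Of 12 endothelial markers 6 were lower and 1 higher, although their sum was higher (3103 ± 345 against 1517 ± 172), and of 8 Schwann cell markers 4 were lower and 2 higher. These 4 lists did not pass (adjusted p = 0.409, 0.534, 0.32 and 0.534, limma camera). Of 40 lists 4 passed with higher and 12 with lower genes in DPP4+ cells, and 1 and 1 with an estimated correlation. Among the 12, the medians of general progenitor markers, collagens, matrix proteases and chemokines turned from -0.49, -0.75, -0.60 and -0.31 to above 0 with quantile normalization or with totals set equal, and that of ribosome biogenesis genes shrank from -0.71 to -0.10 with totals set equal.

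In all, 5052 genes were higher and 4730 lower in DPP4+ cells at 22 °C, 9782 of 13057, of which 1799 and 1733 differed at least 2-fold on the fitted scale; 9960 had an unadjusted p under 0.05. Of the receptors used to define progenitors, Pdgfra stood at 11512 ± 419 in DPP4+ cells and 9894 ± 641 in DPP4- cells (log2 difference 0.22, adjusted p = 0.0142, limma), and Pdgfrb, which was sorted for, at 2942 ± 226 and 4126 ± 333 (log2 difference -0.49, adjusted p = 6.29e-06, limma). The alarmin Il33 was 1.75-fold lower in DPP4+ cells (1121 ± 159 against 1962 ± 478, adjusted p = 0.00155, limma), and the chemokine Ccl2 did not pass (11398 ± 2630 against 10291 ± 1362, adjusted p = 0.495, limma). The adipocyte hormone Adipoq was 16.5-fold higher in DPP4+ cells (332 ± 51.8 against 20.1 ± 11.7) and the beta-3 adrenergic receptor Adrb3 17.0-fold higher (92.3 ± 9.37 against 5.42 ± 2.80), while Trarg1, an adipocyte protein of glucose transporter traffic, was 5.10-fold lower. Of 14 mature adipocyte genes 10 were higher and 2 lower (11 and 2 adjusted over the list alone), and the list did not pass (adjusted p = 0.0988, limma camera). The deposited values of the populations differ in total, 10.2 to 11.5 M in DPP4+ and 16.3 to 17.3 M in DPP4- libraries at 22 °C. With totals set equal the median of all genes moved from 0.03 to 0.64 and the counts became 9107 higher and 2039 lower, Pdgfra rose to 0.83 in place of 0.22, Pdgfrb turned to 0.13, Il33 no longer passed (-0.17) and Ccl2 passed (0.74 in place of 0.13).

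The populations were compared again in mice kept at 6 °C. Sptssb, a subunit of serine palmitoyltransferase, had 1240 ± 220 normalized reads (SD, n = 5) in DPP4+ cells and 0.541 ± 0.830 (n = 5) in DPP4- cells, a ratio of 2292 with a 95% counting interval of 674 to 20103. The renin gene Ren1 stood at 906 ± 200 against 1.52 ± 2.27, Ramp3, a partner of calcitonin-family receptors, at 849 ± 198 against 1.73 ± 1.13, and the vitamin D receptor Vdr at 3331 ± 750 against 13.6 ± 9.76. Inhba, an activin subunit, was 200-fold higher in DPP4+ cells at 1639 ± 386. Lamc3 was 508-fold lower and Gucy1a1, a subunit of the nitric oxide receptor guanylate cyclase, 120-fold lower (2.16 ± 1.63 against 259 ± 57.9).

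Dpp4 remained 164-fold higher in DPP4+ cells in the cold (10035 ± 2091 against 61.3 ± 42.4, adjusted p = 5.12e-14, limma), and all 18 DPP4+ progenitor markers were higher (18 adjusted over the list alone). The DPP4+ marker list had adjusted p = 4.51e-09 (limma camera), and adjusted p = 0.255 with an estimated correlation. Of 19 adipogenic regulators, 13 were lower in DPP4+ cells and 2 higher (13 and 2 adjusted over the list alone), among them Pparg, the master regulator of adipogenesis (73.6 ± 14.8 against 313 ± 48.1), and the transcription factor Sox9 (159 ± 17.2 against 2516 ± 304). The adipogenic regulator list had adjusted p = 0.00844 (limma camera), and adjusted p = 0.255 with an estimated correlation. Committed preadipocyte markers were lower in 14 of 17 cases and higher in 2 (14 and 2 adjusted over the list alone), with both corrections passed (adjusted p = 2.96e-07, limma camera; adjusted p = 0.0352 with an estimated correlation). Nuclear oxidative phosphorylation genes were higher in 33 of 44 cases and lower in none (33 and none adjusted over the list alone; median 0.31). The oxidative phosphorylation list had adjusted p = 0.000342 (limma camera), and adjusted p = 0.712 with an estimated correlation. Cell cycle genes were higher in 30 of 33 cases and lower in 1 (30 and 1 adjusted over the list alone). The cell cycle list had adjusted p = 1.14e-09 (limma camera), and adjusted p = 0.255 with an estimated correlation. Interferon-stimulated genes were lower in 25 of 27 cases and higher in 1 (25 and 1 adjusted over the list alone). The interferon list had adjusted p = 1.3e-09 (limma camera), and adjusted p = 0.406 with an estimated correlation. Immediate early and dissociation genes were lower in 25 of 27 cases and higher in 2 (25 and 2 adjusted over the list alone; median -1.78). The immediate early list had adjusted p = 1.17e-08 (limma camera), and adjusted p = 0.358 with an estimated correlation. Beside these groups, 7 of 12 endothelial markers were lower and 3 higher, and 6 of 15 pericyte and smooth muscle markers were lower and 6 higher, without a call for either list (adjusted p = 0.607 and 0.824, limma camera). Lymphocyte markers summed to 41.6 ± 20.5 against 308 ± 344, with DPP4- cold library 2 at 919, and this list did not pass either (adjusted p = 0.343, limma camera). Of 40 lists 3 passed with higher and 10 with lower genes, and 0 and 1 with an estimated correlation. Among the 10, the median of matrix proteases turned from -0.61 to 0.03 with quantile normalization and that of ribosome biogenesis genes from -0.29 to 0.17 with totals set equal. With totals set equal the median of adipogenic regulators shrank from -0.61 to -0.14 and that of oxidative phosphorylation genes grew from 0.31 to 0.78.

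In the cold Il33 stood 2.50-fold higher in DPP4+ than in DPP4- cells (5286 ± 665 against 2118 ± 679, adjusted p = 4.71e-06, limma), the reverse of its order at 22 °C, and Adrb3 stood 7.84-fold lower (1.06 ± 0.797 against 8.30 ± 5.43). Ucp1, the uncoupling protein of heat-producing adipocytes, was 5.94-fold higher in DPP4+ cells (59.8 ± 13.6 against 10.1 ± 7.37). Pdgfra (5287 ± 462 against 10676 ± 1323) and Pdgfrb (1505 ± 80.7 against 4124 ± 543) were both lower in DPP4+ cells. Ccl2 was 1.33-fold higher (adjusted p = 0.0343, limma), a call lost without each of 5 single libraries, with sample weights (log2 difference 0.36 in place of 0.40) and after a GC content and length correction. In all 5031 genes were higher and 4662 lower, 9693 of 13057, and the log2 differences of the populations at 6 °C and at 22 °C correlated across genes (Pearson r = 0.856, Spearman rho = 0.818; genes are not independent replicates). Of 8015 genes that passed at both temperatures 7554 had the same direction. With totals set equal the median of all genes moved from 0.03 to 0.50 and the counts became 8240 higher and 2461 lower.

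Which genes responded to 24 h of cold in DPP4+ cells was asked next. Sptssb had no read in the 5 libraries at 22 °C and 1240 ± 220 normalized reads (SD, n = 5) at 6 °C, at least 3064-fold higher against a floor of 3 reads over the group. Ren1 rose from 0.276 ± 0.379 to 906 ± 200, a ratio of 3277 with a 95% counting interval of 929 to 27724. Dio2, the deiodinase that activates thyroid hormone in brown fat, rose 556-fold from 9.56 ± 4.82 to 5312 ± 1140 (adjusted p = 2.93e-12, limma). Ramp3 rose from 1.83 ± 1.69 to 849 ± 198, the cytokine Il11 143-fold to 2977 ± 626, the cystine transporter Slc7a11 49.9-fold to 4027 ± 943 and Vdr 28.8-fold to 3331 ± 750. Cemip fell 56.7-fold from 12532 ± 1286 to 221 ± 45.7, the orphan receptor Gpr176 36.0-fold from 1216 ± 128 to 33.8 ± 6.56, and the cardiac transcription cofactor Lbh 22.2-fold from 1563 ± 183 to 70.5 ± 9.70. For each of these genes the 5 cold libraries did not overlap with the 5 libraries at 22 °C, which the naming rule required of the largest rises and falls. Over all tested genes 38.4% were apart in this way.

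Adrenergic receptors and cAMP genes were then examined in the cold. Adrb3 (Entrez gene 11556, GRCm38 chromosome 8, 27225776 to 27230845) fell 87.2-fold in DPP4+ cells, from 92.3 ± 9.37 to 1.06 ± 0.797 normalized reads (adjusted p = 2.63e-11, limma). The alpha-1D receptor Adra1d fell from 231 ± 21.8 to 16.1 ± 3.33. The beta-1 receptor Adrb1 was below the level required for testing (4.88 ± 1.78 at 22 °C and 2.65 ± 2.44 at 6 °C). Of 19 cAMP and CREB target genes 10 rose and 2 fell (11 and 2 adjusted over the list alone; median 0.52). Those that rose included the cAMP phosphodiesterases Pde4d (126 ± 21.5 to 2051 ± 443) and Pde4b (57.2 ± 3.93 to 303 ± 44.0) and the cAMP-responsive repressor Crem (150 ± 28.3 to 1404 ± 237). The cAMP target list had adjusted p = 0.00285 (limma camera), and adjusted p = 0.556 with an estimated correlation. Among adrenergic receptors and cAMP signalling components 6 of 20 rose and 9 fell (6 and 10 adjusted over the list alone), and the list did not pass (adjusted p = 0.229, limma camera).

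Ribosome biogenesis genes rose in 27 of 28 cases and fell in none (27 and none adjusted over the list alone; median 0.43), with the pre-ribosomal factors Bop1 at 366 ± 26.3 and 667 ± 68.5 and Nop2 at 599 ± 44.7 and 962 ± 122. The ribosome biogenesis list had adjusted p = 3.9e-08 (limma camera), and adjusted p = 0.556 with an estimated correlation. Glycolysis genes rose in 12 of 18 cases and fell in 2 (13 and 2 adjusted over the list alone), led by the lactate exporter Slc16a3 (74.8 ± 5.17 to 614 ± 133), with lactate dehydrogenase Ldha at 3702 ± 105 and 5935 ± 754. The glycolysis list had adjusted p = 0.000528 (limma camera), and adjusted p = 0.378 with an estimated correlation. Nuclear oxidative phosphorylation genes rose in 21 of 44 cases and fell in none (21 and none adjusted over the list alone). The oxidative phosphorylation list had adjusted p = 0.00176 (limma camera), and adjusted p = 0.708 with an estimated correlation. Ribosomal protein genes rose in 12 of 38 cases and fell in none (11 and none adjusted over the list alone). The ribosomal protein list had adjusted p = 0.00285 (limma camera), and adjusted p = 0.708 with an estimated correlation. Its median was 0.15, and 0.03 with quantile normalization. Unfolded protein response genes rose in 14 of 24 cases and fell in 6 (15 and 6 adjusted over the list alone), with the chaperones Hspa5 at 13888 ± 1191 and 27337 ± 2042 and Hyou1 at 1756 ± 34.8 and 3865 ± 440. The unfolded protein list had adjusted p = 0.0066 (limma camera), and adjusted p = 0.556 with an estimated correlation. Cold-inducible and heat shock genes rose in 8 of 12 cases and fell in none (8 and none adjusted over the list alone). The heat shock list had adjusted p = 0.00524 (limma camera), and adjusted p = 0.556 with an estimated correlation. Genes of the type 2 immune response rose in 6 of 10 cases and fell in none (6 and none adjusted over the list alone). Il33 (Entrez gene 77125, GRCm38 chromosome 19, 29925113 to 29960718) rose 4.72-fold from 1121 ± 159 to 5286 ± 665 (adjusted p = 2.71e-08, limma) and its receptor gene Il1rl1 9.36-fold from 1291 ± 317 to 12092 ± 1964. The type 2 list had adjusted p = 0.0143 (limma camera), and adjusted p = 0.556 with an estimated correlation. Ccl2 did not pass (11398 ± 2630 at 22 °C and 13144 ± 3041 at 6 °C, adjusted p = 0.332, limma).

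Cell cycle genes fell in 17 of 33 cases and rose in 1 (17 and 1 adjusted over the list alone; median -0.50), including the cyclins Ccnb2 (211 ± 21.8 to 87.5 ± 11.8) and Ccnd1 (533 ± 42.3 to 337 ± 70.3) and the helicase subunit Mcm6 (477 ± 43.0 to 309 ± 31.5). The cell cycle list had adjusted p = 0.00285 (limma camera), and adjusted p = 0.646 with an estimated correlation. Wnt genes fell in 14 of 28 cases and rose in 6 (14 and 6 adjusted over the list alone), with the receptor Fzd4 at 1142 ± 94.7 and 303 ± 11.1, the secreted target Wisp1, now named Ccn4, at 407 ± 35.5 and 65.7 ± 12.5, and the pathway inhibitor Nkd2 at 159 ± 14.7 and 35.7 ± 6.99. The Wnt list had adjusted p = 0.00756 (limma camera), and adjusted p = 0.378 with an estimated correlation. Collagens and matrix genes fell in 16 of 43 cases and rose in 6 (16 and 6 adjusted over the list alone), with thrombospondin Thbs1 at 43776 ± 4562 and 5006 ± 800 and the collagen cross-linking oxidase Lox at 33316 ± 2109 and 17673 ± 2661. The matrix list had adjusted p = 0.0468 (limma camera), and adjusted p = 0.708 with an estimated correlation. Pdgfra fell 2.18-fold from 11512 ± 419 to 5287 ± 462 and Pdgfrb 1.95-fold from 2942 ± 226 to 1505 ± 80.7, while Dpp4 did not pass (adjusted p = 0.559, limma). Markers of pericytes and smooth muscle fell in 6 of 15 cases and rose in 2 beside these groups, and their sum fell from 11410 ± 1159 to 6478 ± 1160. Among those that fell was the muscle actin regulator Lmod1 (105 ± 21.6 to 0.304 ± 0.423, a ratio of 347 with a 95% counting interval of 91.4 to 2741). The list did not pass (adjusted p = 0.132, limma camera). Schwann cell markers fell in 3 of 8 cases, and endothelial markers rose in 3 of 12 and fell in 1. Neither list passed (adjusted p = 0.352 and 0.848, limma camera).

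Ucp1 (Entrez gene 22227, GRCm38 chromosome 8, 83290348 to 83298456) rose 72.8-fold in DPP4+ cells in the cold, from 0.822 ± 0.581 to 59.8 ± 13.6 normalized reads (adjusted p = 9.32e-11, limma). Mature adipocyte genes did not rise beside it: 6 of 14 fell and none rose (7 and none adjusted over the list alone; median -0.77). The mature adipocyte list had adjusted p = 0.011 (limma camera), and adjusted p = 0.646 with an estimated correlation. The lipid droplet gene Plin1 did not pass (342 ± 37.1 at 22 °C and 172 ± 41.2 at 6 °C, adjusted p = 0.16, limma), although its 5 cold libraries (107 to 218) lay below the 5 at 22 °C (289 to 389). The fit shares the spread of a gene over all groups. For Plin1 that spread includes DPP4- library 1 at 22 °C, with 2.70 normalized reads against 33.8 to 58.5 in the others of its group. The missing call is therefore no sign that Plin1 was unchanged in DPP4+ cells. The activin receptor Acvr1c fell from 27.2 ± 3.46 to 5.11 ± 0.775, and the triglyceride lipase Pnpla2 fell from 495 ± 30.9 to 385 ± 23.8. Of 10 thermogenic adipocyte genes 3 rose and 2 fell (3 and 2 adjusted over the list alone), and the list did not pass (adjusted p = 0.454, limma camera). In all 3069 genes rose and 2954 fell in DPP4+ cells, 6023 or 46.1% of 13057, of which 359 and 628 changed at least 2-fold. Without DPP4+ cold library 5, which differed most from its group, the counts were 3110 and 3055, and with totals set equal 42.0% of the calls were higher in place of 51.0%.

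**Figure D2:**
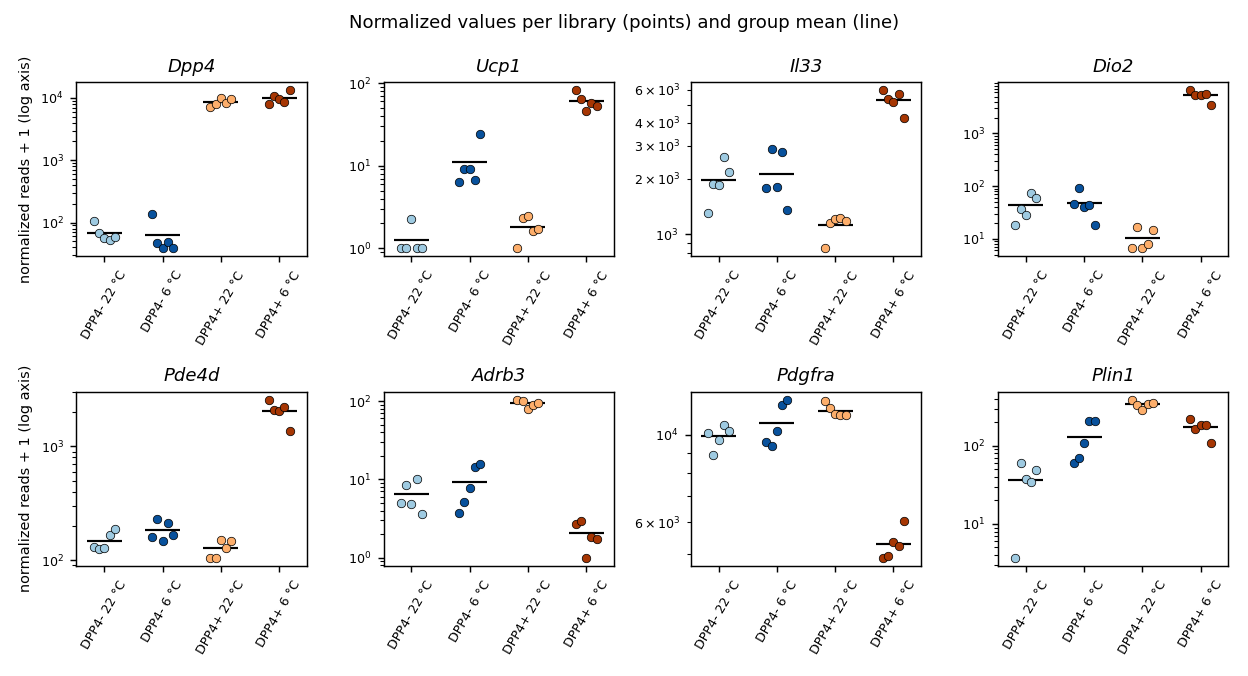
Normalized reads plus 1 (y axis, logarithmic) of 8 genes in each of the 20 libraries, by sorted population and temperature on the x axis; points are libraries and lines are group means, n = 5. Dio2, Pde4d, Il33 and Ucp1 rise in DPP4+ cells at 6 °C (Dio2 from 9.56 to 5312), Adrb3 and Pdgfra fall there, and Plin1 is higher at 6 °C in DPP4- cells while in DPP4+ cells it does not pass.

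The same question was asked of DPP4- cells. Plin1, which coats lipid droplets, rose 3.62-fold in the cold, from 35.8 ± 21.0 to 130 ± 73.0 normalized reads (SD, n = 5), and the fatty acid transporter Cd36 rose 2.57-fold from 2355 ± 972 to 6045 ± 1266. The endoplasmic reticulum protein Reep6 rose 3.20-fold, the stress hormone Gdf15 1.97-fold and the growth factor binding protein Igfbp5 1.84-fold. The estrogen sulfotransferase Sult1e1 fell 2.64-fold from 3065 ± 1210 to 1160 ± 393, the matrix proteoglycan Aspn 2.30-fold from 4314 ± 449 to 1878 ± 287 and the secreted Wnt modulator Sfrp2 2.11-fold. In all 259 genes rose and 422 fell, 681 or 5.22% of 13057, of which 24 and 28 changed at least 2-fold; 2680 genes had an unadjusted p under 0.05.

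Collagens and matrix structural genes fell in 16 of 43 cases and rose in none (26 fell and 1 rose adjusted over the list alone; median -0.30). Fibronectin Fn1 fell 1.76-fold from 49050 ± 4268 to 27821 ± 3745 (adjusted p = 0.000153, limma), and the collagens Col16a1 and Col5a2 fell 1.45-fold and 1.31-fold. The matrix list had adjusted p = 4.12e-14 (limma camera), and adjusted p = 0.106 with an estimated correlation. Its median was -0.14 with quantile normalization and -0.20 with totals set equal. Unfolded protein response genes rose in 8 of 24 cases and fell in none (14 and none adjusted over the list alone; median 0.27) and passed with both corrections (adjusted p = 1.31e-09, limma camera; adjusted p = 0.0248 with an estimated correlation). The chaperone cofactor Sdf2l1 rose from 113 ± 14.6 to 209 ± 49.8, Creld2 from 369 ± 40.8 to 533 ± 54.6, Hyou1 from 1345 ± 46.8 to 1819 ± 205 and the secreted stress factor Manf from 1500 ± 77.1 to 1856 ± 87.1. BMP signalling genes fell in 3 of 24 cases and rose in none (8 and none adjusted over the list alone), among them the BMP antagonist Chrd and Gdf10. The BMP list had adjusted p = 0.00445 (limma camera), and adjusted p = 0.184 with an estimated correlation. Its median of -0.26 was -0.17 with totals set equal. DPP4+ progenitor markers fell in 3 of 18 cases (5 adjusted over the list alone). The DPP4+ marker list had adjusted p = 0.015 (limma camera), and adjusted p = 0.675 with an estimated correlation. Dpp4 itself did not pass (67.9 ± 21.6 and 61.3 ± 42.4, adjusted p = 0.606, limma).

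Mature adipocyte genes rose in 4 of 14 cases and fell in none (10 and none adjusted over the list alone; median 0.79). Besides Plin1 these were the carbonic anhydrase Car3 (219 ± 127 to 721 ± 315), the hormone gene Retn (9.01 ± 3.14 to 18.1 ± 5.57) and the triglyceride synthesis enzyme Dgat2 (84.1 ± 12.3 to 133 ± 28.8). The mature adipocyte list had adjusted p = 6.84e-07 (limma camera), and adjusted p = 0.242 with an estimated correlation. Of 10 thermogenic adipocyte genes 3 rose and none fell (4 and none adjusted over the list alone). The thermogenic list had adjusted p = 0.00445 (limma camera), and adjusted p = 0.106 with an estimated correlation. Ucp1 rose from 0.252 ± 0.563 to 10.1 ± 7.37, a ratio of 40.0 with a 95% counting interval of 7.35 to 1734, and the brown fat transcription factor Prdm16 rose 1.42-fold. Within each temperature the mature adipocyte genes varied together between DPP4- libraries, with a mean pairwise correlation of 0.407 across the list, above the 95th percentile of 0.0723 for random lists matched on mean level. Mesothelial markers, too few to test as a list, summed to 80.8 ± 16.7 in the cold and 37.5 ± 12.7 at 22 °C, with the libraries apart (59.0 to 104 against 25.7 to 55.3). Much of this was Lrrn4, chosen after its values were seen (36.9 ± 18.3 against 8.42 ± 3.92). Pdgfra, Pdgfrb, Il33, Ccl2 and Adrb3 did not pass in DPP4- cells, with Il33 at 1962 ± 478 and 2118 ± 679 (adjusted p = 0.844, limma) and Ccl2 at 10291 ± 1362 and 9919 ± 2207 (adjusted p = 0.848, limma). The call of Plin1 (adjusted p = 0.0423, limma) was lost without each of 5 single libraries, and Retn was not called by edgeR or DESeq2.

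DPP4- cold library 2 held more reads of blood cell markers than the other 4 of its group, with 2123 normalized reads over 14 granulocyte and mast cell genes against 8.23 to 147. None of the granulocyte, lymphocyte or macrophage lists passed in DPP4- cells. Without this library 343 genes rose and 471 fell, and without library 3 of the same group 163 rose and 317 fell. With only the groups of the contrast in the fit 102 rose and 290 fell, and with sample weights 147 and 287. With totals set equal, which moved the median of all genes to 0.10, 915 genes rose and 227 fell in place of 259 and 422.

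Whether the cold response differed between the populations was tested as an interaction. Sptssb, Dio2, Ren1 and Il11 responded more in DPP4+ cells, with differences of the log2 cold effect of 11.19, 8.93, 8.80 and 7.70 (standard errors 0.64, 0.58, 0.60 and 0.31). Of these edgeR did not call Ren1. The steroidogenic regulator Star had a difference of 4.83. Adrb3 (-6.02), Cemip (-5.95) and the WD repeat gene Wdr86 (-5.32) had negative differences. The cold effect on Il33 differed by 2.15 (adjusted p = 9.08e-06, limma), on Pdgfra by -1.23 (adjusted p = 7.21e-09, limma) and on Pdgfrb by -0.96 (adjusted p = 4.47e-07, limma), while Ccl2 (adjusted p = 0.396, limma) and Dpp4 (adjusted p = 0.357, limma) did not pass, except that Dpp4 passed without DPP4- cold library 1 (0.84 in place of 0.51). Ucp1 differed by 2.06 (adjusted p = 0.00447, limma) on the log2(value + 1) scale, a call that edgeR and DESeq2 (1.16 and 1.36) and a pseudocount of 0.1 (0.78) did not make.

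Ribosome biogenesis genes responded more in DPP4+ cells in 20 of 28 cases and less in none (20 and none adjusted over the list alone). The ribosome biogenesis list had adjusted p = 9.76e-06 (limma camera), and adjusted p = 0.633 with an estimated correlation. For cAMP and CREB targets the counts were 9 and 1 of 19 (9 and 1 adjusted over the list alone), with Pde4d at 3.69. The cAMP target list had adjusted p = 0.00147 (limma camera), and adjusted p = 0.531 with an estimated correlation. For glycolysis genes they were 10 and 1 of 18 (10 and 1 adjusted over the list alone), with Slc16a3 at 3.27. The glycolysis list had adjusted p = 0.00147 (limma camera), and adjusted p = 0.448 with an estimated correlation. Mature adipocyte genes had lower cold effects in DPP4+ cells in 11 of 14 cases and a higher one in none (12 and none adjusted over the list alone; median -1.69), with Trarg1 at -2.05. The mature adipocyte list had adjusted p = 1.49e-05 (limma camera), and adjusted p = 0.463 with an estimated correlation. Cell cycle genes were lower in 14 of 33 cases and higher in 1 (16 and 1 adjusted over the list alone), with Mcm7 at -0.67. The cell cycle list had adjusted p = 0.00147 (limma camera), and adjusted p = 0.633 with an estimated correlation. Wnt genes were lower in 12 and higher in 6 of 28 cases (12 and 6 adjusted over the list alone), with Fzd4 at -2.13. The Wnt list had adjusted p = 0.0375 (limma camera), and adjusted p = 0.448 with an estimated correlation. The median for ribosome biogenesis genes moved from 0.38 to 0.24 with totals set equal, and that for glycolysis genes from 0.31 to 0.16.

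Across the 13057 genes the log2 cold effects in the 2 populations had Pearson r = 0.0199 (jackknife standard error 0.0431 over the libraries) and Spearman rho = 0.0441. Of 394 genes that passed in both populations, 263 moved the same way. Both rose in 90 cases, where independent calls would give 60.9, and both fell in 173, where they would give 95.5. The others went opposite ways, 74 with a rise in DPP4+ cells and 57 with a fall, where independent calls would give 99.2 and 58.6. The cold effect itself differed for 4329 genes, 2192 with a higher and 2137 with a lower effect in DPP4+ cells. With totals set equal the median of all genes moved from 0.01 to -0.13 and the counts became 1128 and 3061.

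**Figure D3:**
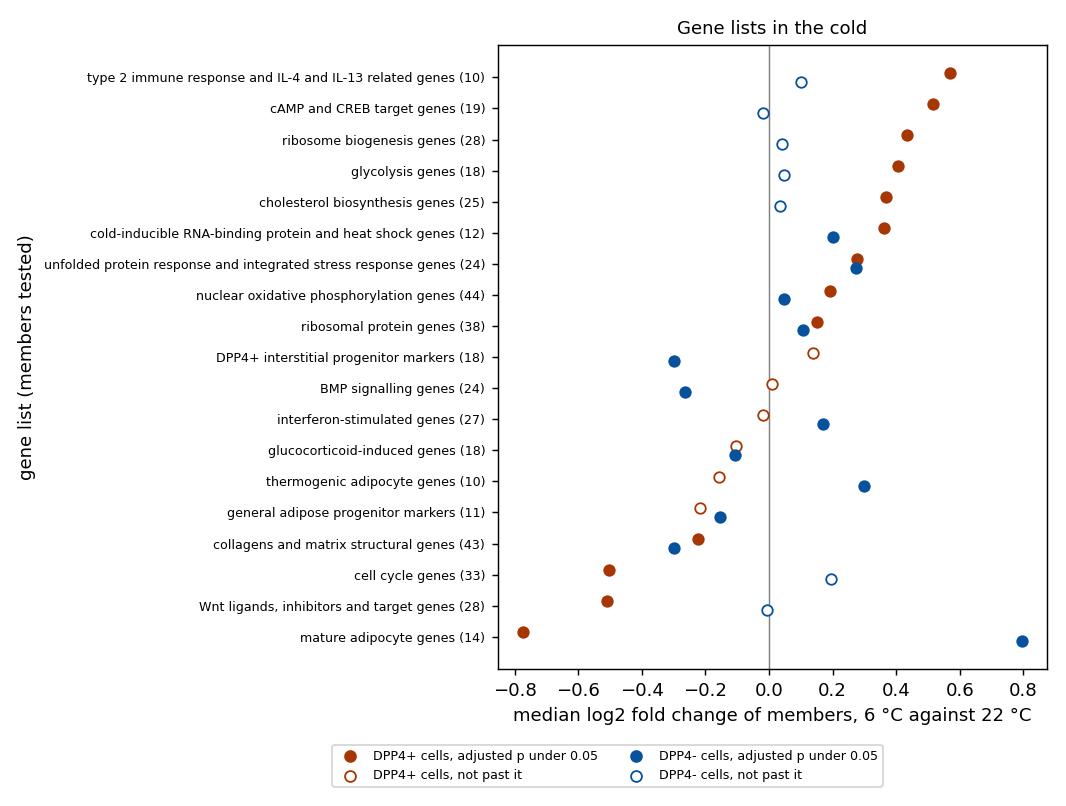
Median log2 fold change in the cold (x axis, 6 °C against 22 °C) of the tested members of 19 gene lists (y axis, number tested in parentheses) in DPP4+ and DPP4- cells; filled points are lists with an adjusted p under 0.05 in camera with the preset correlation. Mature adipocyte genes lie at -0.77 in DPP4+ and 0.79 in DPP4- cells, and unfolded protein response genes at 0.28 and 0.27.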

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

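Of the tests weighed in this part, adipocyte RNA in DPP4+ cells was tested only after the results were seen, and thinning, the GC content correction and the removal of 2 libraries were added to the plan.

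The effect of cold differed between the populations, by the interaction test in limma, for 63 of the 73 genes named in the cold comparisons, with 31 differences positive and 32 negative. Most of these genes were chosen for their cold changes or for this difference, which raises the share by construction; over all 13057 genes it was 33.2%. The values below are log2 cold effects in DPP4+ cells minus those in DPP4- cells, on the log2(value + 1) scale. Where a group had few or no reads, as for Sptssb and Ren1, the size of the difference depends on the value added before the log. Above 4 were Sptssb (11.19), Dio2 (8.93), Ren1 (8.80), Ramp3 (8.46), Il11 (7.70), Slc7a11 (5.90), Nppc (5.34), Vdr (5.04) and Star (4.83). Between 2 and 4 were Pde4d (3.69), Il1rl1 (3.38), Crem (3.31), Slc16a3 (3.27), Cxcl14 (2.96), Clcf1 (2.60), Pde4b (2.32), Il33 (2.15) and Ucp1 (2.06). Smaller positive differences were found for Arntl (1.18), Sfrp2 (0.97), Vegfa (0.97), Aspn (0.80), Hyou1 (0.70), Hspa5 (0.69), Nop2 (0.65), Chrd (0.60), Ldha (0.60), Bop1 (0.59), Creld2 (0.51), Fn1 (0.49) and Manf (0.40).

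Below -3 were Adrb3 (-6.02), Lmod1 (-5.99), Cemip (-5.95), Wdr86 (-5.32), Gpr176 (-4.83), Lbh (-4.27), Adra1d (-4.11), Gucy1b1 (-3.88), Thbs1 (-3.19), Car3 (-3.13) and Plin1 (-3.10). Between -3 and -2 were Reep6 (-2.64), Acvr1c (-2.41), Wisp1 (-2.32), Adm (-2.28), Nkd2 (-2.20), Fzd4 (-2.13) and Trarg1 (-2.05). The others were Per3 (-1.50), Fabp4 (-1.31), Cxcl12 (-1.28), Ccnb2 (-1.25), Pdgfra (-1.23), Cd36 (-1.10), Retn (-1.09), Gdf15 (-1.05), Pdgfrb (-0.96), Prdm16 (-0.79), Mcm6 (-0.72), Mcm7 (-0.67), Pnpla2 (-0.64) and Lox (-0.46).

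Single libraries lay far from the other 4 of their group in 28 of 307 tests (9.12%), 21 of them of single genes, where chance gives about 1 in 20 groups (5%). In DPP4- cold library 2 the markers of macrophages summed to 806 normalized reads (202 to 355 in the others), of lymphocytes to 919 (97.1 to 205) and of granulocytes and mast cells to 2123 (8.23 to 147), and Ren1 stood at 5.45 (0 to 1.34). In DPP4- cold library 5 Ucp1 stood at 23.0 (5.36 to 8.18) and endothelial markers summed to 1002 (1473 to 1659). In DPP4- cold library 1 Dpp4 stood at 137 (37.8 to 47.1) and Schwann cell markers summed to 457 (635 to 702). DPP4+ cold library 5 was low in Cemip at 142 (227 to 254), Clcf1 at 105 (162 to 180) and Wisp1 at 44.1 (67.1 to 75.9).

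At 22 °C, DPP4- library 1 was high in Dpp4 at 105 (52.2 to 67.6), Sfrp2 at 13350 (8365 to 9691) and Sult1e1 at 5146 (2157 to 3006), and low in Trarg1 at 58.1 (100.3 to 117). DPP4- library 2 was high in Cemip at 21.0 (4.05 to 6.43) and library 3 in granulocyte and mast cell markers at 407 (10.8 to 113). Ren1 at 1.501 in library 2 and Ucp1 at 1.26 in library 3 were each a single read against 0 in the others, which the test always marks, so that these 2 of the 28 carry no weight. DPP4- library 4 was high in Aurka at 10.7 (6.01 to 6.75) and in Schwann cell markers at 1088 (683 to 757). DPP4- library 5 was high in Ccl2 at 12607 (8986 to 10031), Hyou1 at 1427 (1310 to 1330) and Lamc3 at 1283 (817 to 918). In DPP4+ libraries at 22 °C, library 1 stood at 842 for Il33 (1149 to 1231) and at 550.3 for Pnpla2 (478 to 487), library 3 at 425 for Cxcl14 (486 to 502) and library 4 at 20.7 for Star (24.9 to 26.2).

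Cold changed 6023 genes in DPP4+ cells and 681 in DPP4- cells, a ratio of 8.84. The ratio was 4.96 with totals set equal, 17.6 with only the groups of the contrast in the fit and 17.9 with sample weights. Unequal depth as the whole cause is argued against by thinning every library to 8.49 M reads, after which the ratio was at least 9.44 in each of 10 draws, and a GC content or length trend by a ratio of 9.44 after correction. Without DPP4- cold library 2 and DPP4+ cold library 5 the ratio was 5.73. Over all tested genes the median size of the log2 cold effect was 0.249 in DPP4+ cells and 0.123 in DPP4- cells. The test of a difference between the cold effects was planned. That the response is larger in DPP4+ cells was found and tested on the same libraries and remains a hypothesis.

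In DPP4- cells Ucp1 and 4 of 14 mature adipocyte genes rose in the cold (list adjusted p = 6.84e-07, limma camera; adjusted p = 0.242 with an estimated correlation), and the sort for PDGFRb should remove adipocytes. The adipocyte genes varied together between DPP4- libraries within a temperature (mean pairwise correlation 0.407; 10000 random lists had a median of -0.0052 and a 95th percentile of 0.0723). This is consistent with adipocyte RNA carried over in amounts that differ between libraries, and shared regulation in the cells predicts the same. Of the abundant members, Car3 reached 721 ± 315 normalized reads and Plin1 130 ± 73.0 in the cold. In DPP4+ cells the list had a median of -0.77, with 6 members lower and none higher, so no rise of adipocyte RNA in the cold was seen there. The list still took 0.0201% of the normalized reads of DPP4+ cold libraries, against 0.0219% in DPP4- cold libraries. The totals of these groups differ, and as sums the list had 2279 ± 301 and 3451 ± 560 normalized reads. Neither measure tells which cells the reads came from. The fall of the list therefore cannot decide whether carried-over adipocyte RNA was the source of Ucp1 in DPP4+ cells.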

How the results depend on the processing

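The settings with totals set equal, with a GC content and length correction, with thinned reads and with both doubted libraries out (DPP4- cold library 2 and DPP4+ cold library 5) were chosen after the data were seen. Of 3778 values of 151 results for named genes under the alternatives, 3702 kept their direction and their side of the threshold, 53 kept their direction and lost their call, 3 gained a call and 20 changed sign. With totals set equal 915 genes were higher and 227 lower in the cold in DPP4- cells, 1128 higher for the difference of the cold effects, 9107 higher and 2039 lower between the populations at 22 °C, and 8240 and 2461 in the cold; the all-gene median moved by construction. In DPP4- cells 102 genes were higher with only the groups of the contrast in the fit and 147 with sample weights. There 469 were higher with both doubted libraries out, and 277 lower with quantile normalization. The cause was not tested. The main fit shares the spread of a gene over all groups. The median SD of log2 values was 0.184 in DPP4- cells in the cold and 0.163 at 22 °C. In DPP4+ cells it was 0.155 and 0.116. With only the groups of the contrast in the fit, 392 genes were called in DPP4- cells in place of 681. In DPP4+ cells 6895 were called in place of 6023. The main fit may therefore call too many genes in DPP4- cells. With a filter at a mean of 100, which tests fewer genes, 1920 genes were lower in DPP4+ cells in the cold, 1352 lower for the difference, and 3248 higher between the populations at 22 °C.

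With an estimated correlation 0 lists were called up and 0 down in DPP4+ cells in the cold, 1 and 0 in DPP4- cells, 0 and 0 for the difference, 1 and 1 between the populations at 22 °C, and 0 and 1 in the cold; the cause was not tested. With quantile normalization 3 lists were called down in DPP4- cells, 7 down for the difference, 5 down between the populations at 22 °C, and 5 up and 5 down in the cold; the cause was not tested.

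Leaving out single libraries gave 163 (without DPP4- cold library 3) to 343 (without DPP4- cold library 2) genes higher in DPP4- cells. It gave 2 to 5 lists down in DPP4- cells, 3 to 6 up for the difference and 3 to 5 up between the populations in the cold. The concordance of the cold effects ranged from -0.0035 (without DPP4- cold library 1) to 0.043 (without DPP4- cold library 5). In DPP4- cells, where none of the 3 genes passed, Ccl2 ranged from -0.18 to 0.0050 over left-out libraries and was 0.031 with quantile normalization and 0.027 with equal totals. Il33 ranged from -0.052 to 0.23 and was -0.040 with both doubted libraries out. Pdgfrb ranged from -0.066 to 0.055 there. It was 0.047 with quantile normalization, 0.091 with equal totals, 0.0016 with sample weights, 0.0065 in edgeR, 0.055 with both doubted libraries out and 0.0072 after the GC content and length correction. Between the populations at 22 °C Pdgfrb was 0.13 with equal totals, a scaling that moved the median of all genes there from 0.03 to 0.639 by construction.

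With the replicate number as a block 3156 genes were higher and 3025 lower in DPP4+ cells in the cold, 333 and 528 in DPP4- cells, and no named gene changed. Whether the numbers pair the samples was left open: after removal of group means same-numbered libraries correlated over 0.1 in 2 of 5 cases in each of 4 pairs of groups. Same-numbered DPP4+ and DPP4- libraries correlated at 0.029 to 0.156 at 22 °C and at 0.0166 to 0.107 in the cold, where the own number was the best match in 4 of 5 cases (2 of 5 at 22 °C). Between the temperatures same-numbered libraries correlated at -0.00733 to 0.267 in DPP4+ cells and at -0.228 to 0.188 in DPP4- cells. These come from mice housed apart in temperature, so a correlation at the same number need not mean a shared animal. Whether the number marks a batch was not tested. Depth limits genes near the filter, where 1 read is worth 0.622 to 1.88 normalized reads.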

Other observations

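Tests of pericytes and of smooth muscle cells in the DPP4+ sort and of the time or steps per sort were chosen only after the result was seen, as were the alternatives with equal totals and with a GC content and length correction.

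Further lists were examined in DPP4+ cells in the cold. Cholesterol biosynthesis genes rose in 12 of 25 cases and fell in 4 (13 and 4 adjusted over the list alone) (list adjusted p = 0.029, limma camera; adjusted p = 0.798 with an estimated correlation). Chemokines and cytokines rose in 10 of 28 cases and fell in 4, without a call for the list (adjusted p = 0.141, limma camera): Cxcl14, which attracts monocytes, rose 6.80-fold from 478 ± 30.4 to 3249 ± 628 normalized reads and the cytokine Clcf1 6.75-fold, while Cxcl12, a retention signal for leukocytes, fell 2.26-fold. Of 17 circadian clock genes 4 rose and 4 fell, with the activator Arntl at 526 ± 54.6 and 1013 ± 74.1 and Per3, of the repressor arm, at 536 ± 41.5 and 194 ± 40.3 (list adjusted p = 0.922, limma camera). The angiogenic factor Vegfa rose 2.58-fold and the vasodilator peptide Adm fell 5.07-fold, while neither the angiogenic nor the hypoxia list passed (adjusted p = 0.692 and 0.229, limma camera). Nppc, the gene of C-type natriuretic peptide, rose 74.9-fold to 62.1 ± 18.3, and Gucy1b1, a subunit of the nitric oxide receptor, fell 14.7-fold.

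In DPP4- cells other lists passed on small shifts shared by their members. Ribosomal protein genes had a median of 0.11 with 0 of 38 called (adjusted p = 8.08e-06, limma camera; adjusted p = 0.675 with an estimated correlation), and interferon-stimulated genes a median of 0.17 with 1 of 27 called (adjusted p = 0.00199, limma camera; adjusted p = 0.733 with an estimated correlation). With totals set equal these medians were 0.20 and 0.27. Cold-inducible and heat shock genes had 1 of 12 called and 7 adjusted over the list alone (adjusted p = 0.000319, limma camera; adjusted p = 0.305 with an estimated correlation).

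In DPP4+ cells at 22 °C the cell cycle list was higher, the immediate early and interferon lists were lower (adjusted p = 0.196, 0.35 and 0.484 with an estimated correlation, limma camera), and the contractile genes Acta2, Tagln and Cnn1 were higher. Pericytes in the DPP4+ sort, which PDGFRb would not remove, are argued against by 5 of 6 pericyte markers being lower and 0 higher. This holds for a part of the list that was split off after its values were seen. Mcam and Des, which mark both cell types, were put in neither part, and over the whole list 7 of 15 markers were higher and 6 lower. Smooth muscle cells remain open, as 6 of 7 contractile markers were higher and only Myh11, chosen after its values were seen, was lower (77.0 ± 7.12 against 152 ± 59.3 normalized reads). A GC content or length trend is argued against by a cell cycle median of 4.24 after correction, and scaling by a cell cycle median of 4.85 and an immediate early median of -1.24 with equal totals. Different times or steps between tissue and lysis in the 2 sorts could lower the immediate early genes (median -1.85), and the labels give neither, so that this cannot be told apart from a difference of the cells.

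In 100 regroupings of the libraries for each comparison, only the real grouping (1 of 100) reached its count. This argues against chance as the source of the counts in each comparison except the difference of the cold effects. It bounds chance at 1 in 100 and no lower, and it does not test a day or batch shared by a whole group. For the difference it cannot decide, because regrouping also broke up the cold effect in DPP4+ cells and so widened the spread within groups. The real counts were 6023 in DPP4+ cells in the cold against 2566 in the highest other grouping, 681 against 47 in DPP4- cells, 4329 against 2 for the difference, 9782 against 5579 between the populations at 22 °C, and 9693 against 6411 in the cold.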
